A study of Mus musculus with 219 samples.

How the data were processed

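The series holds DNA sequence of 217 single sperm and 2 bulk sperm samples of 1 male mouse, a hybrid of C57BL/6J and CAST/EiJ that carries a humanized and a CAST allele of Prdm9. Per the labels' protocols, sperm were isolated mechanically, the DNA of each was amplified and libraries were made with a modified commercial protocol. Reads were handled with BWA 0.7.15 and the mm10 build, per the submitters' processing notes. The deposited values are base positions: for each crossover, the sperm number, the chromosome and the left and right bound of the interval that contains the breakpoint, per the file headers. The marker set, the filters on markers and the caller are not given in the sources used here, nor is it stated whether positions count from 0 or 1, so coordinates are printed as listed. Marker filters and a minimum number of markers per segment could remove short segments and so lower the number of close pairs.

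The table held 2649 crossovers, 2615 on the autosomes and 34 on the X, and every right bound was above its left bound. Each of the 217 sperm numbers matched the number in 1 sample title. The bulk samples were not analysed here. Depth per sperm is unknown, so its effect on the values could not be assessed. Precision comes from the number of sperm and crossovers, and exact Clopper-Pearson intervals at 95% are given for shares. They cover counting error only.

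Sperm were compared in pairs before any test. A pair was taken as 1 sperm if at least 80% of the autosomal crossovers of the shorter list lay within 200 kb of one in the other list. This held for 1256 and 1265 alone among 23436 pairs. The list of 1265, all 11 of whose crossovers were shared, was kept. This step and the alternative that counts both lists were chosen after seeing the data.

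Chromosome lengths were taken as the largest coordinate of each chromosome over the crossovers and a RefSeq gene table of the same assembly (GRCm38.p6, which is mm10 with patches), 2460 Mb in all. A crossover was placed at the midpoint of its interval. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Dispersion of counts was tested with 100000 multinomial assignments, chromosome rates with exact binomial tests and Benjamini-Hochberg adjustment, and correlations with 100000 permutations. Line parameters came with 2000 bootstraps over sperm. Chromatids with several crossovers were tested by 100000 random assignments to sperm within each chromosome, distances by 10000 permutations of positions, and covariation of chromosomes by 10000 reshufflings of sperm. Shared sites used intervals of up to 10 kb and an overlap of at least 1 bp, against 1000 sets with each interval moved by 50 to 500 kb. Overlapping intervals were chained into sites. Gene tests used 1000 sets, moved by 20 to 200 kb for gene bodies and by 1 to 5 Mb for gene lists, whose clusters are larger. Each interval was moved on its own, so crossovers at a shared site counted as independent. Tests are two-sided unless said otherwise, and 0.05 was the threshold.

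The statistics were tested on simulated data with the real chromosome counts. For 50 sets of independently placed crossovers, 2602 each, p fell below 0.05 in 2 sets for dispersion, in 0 for chromatids with several crossovers and in 2 for distances. With interference built in, all 3 tests passed in 50 of 50 sets. In 20 sets with 300 crossovers planted at shared sites, a mean excess of 279 was recovered, and 0 of 20 sets passed without planting. After removal of 80% of the crossovers near receptor genes, the shortfall estimated over 20 sets was 78.1%, and 0 of 20 sets passed without removal. In the simulations of shared sites and receptor genes, positions were first scattered over several Mb, which smooths local density. They therefore do not show how often local structure of real crossovers would pass these tests.

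Gene positions and names came from the RefSeq table, which gives no strand, exon or sequence as used here. Of 45 listed meiotic symbols, Sws1 had no match, which left 42 distinct autosomal genes. The share near gene starts was therefore replaced by that near either gene end, chosen after seeing the data, and the tests on exons, GC content, the human PRDM9 motif, enriched 8-base sequences and parental haplotype were not run. Named items followed a rule fixed before the data were examined: the 3 highest and 3 lowest chromosomes per Mb, the 10 sites with the most sperm, the 20 protein-coding genes holding most whole intervals and, in each list, up to 5 genes with a midpoint. Ties between sites went to the smaller joint width, which left out 3 of the 8 autosomal sites with 7 sperm, and ties between genes to the higher count per Mb, which left out 5 of the 10 genes with 6 whole intervals. Of the zinc finger genes, 6 are named because of a tie. Naming the leading genes over 500 kb and the other chromosomes in the text, and the alternative positions of paired crossovers, were decided after their values were seen.

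The sample titles give no batch, but the sperm numbers fall into 5 runs (201 to 295, 1201 to 1296, 2204 to 2296, 3233 to 3295 and 4201 to 4264). The comparisons of counts per sperm, chromosome rates, chromatids, distances, positions, paired against single crossovers, covariation, shared sites, gene bodies, gene ends and gene lists were repeated without each run and, except for the binomial and chi-square tests of chromosome rates and the count of pairs under 20 Mb, within each run. Those of gene bodies, gene ends, gene lists and paired crossovers were added after the main values had been seen. Other alternatives were limits on interval width, removal of outlying sperm, removal of crossovers under 5 Mb from another on the chromatid, other windows, other moves and other definitions of overlap.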

Results

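Meiotic crossovers were mapped in single sperm of 1 male mouse, aged 10 weeks, a first-generation hybrid of the laboratory strain C57BL/6J (B6) and the wild-derived strain CAST/EiJ (CAST). PRDM9, the zinc finger protein that binds DNA and directs where recombination starts, was present in a humanized form on one allele and in the CAST form on the other. Each sperm carries 1 product of meiosis, so a change from B6 to CAST sequence along a chromosome marks a crossover. The table listed crossovers sperm by sperm, each placed on mm10 as an interval with a left and a right bound. The 2 bulk sperm samples of the same study were not analysed here. Read depth per sperm is unknown, and the width of the interval is the measure of resolution used here. In 1 pair of sperm, all 11 autosomal crossovers of the shorter list lay within 200 kb of one in the other list, which had 13; the pair was counted as 1 sperm, which left 2602 autosomal and 34 X-chromosomal crossovers. The sample titles number the sperm in 5 runs, and the sperm counted were 68, 39, 35, 37 and 37 in these runs. Because all sperm came from 1 mouse, the tests below say nothing about other mice. Their unit differs: some compare sperm or chromatids, the correlations with length compare chromosomes. The tests of chromosome rates, positions, shared sites and genes take single crossovers as independent, so their p-values do not measure the spread between sperm.

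The intervals were narrow. The median autosomal width was 915.5 bp, with quartiles of 395 and 2135 bp, and 2459 of the 2602 intervals (94.5%) spanned 10 kb or less. The number of crossovers in a sperm was not related to the resolution of its intervals: over all sperm, the correlation with the log10 of the median width was r = -0.0576 (permutation p = 0.399) and rho = -0.0843 (permutation p = 0.217), and r = -0.0610 without the 2 sperm farthest from the median width. Within the 5 runs of sperm numbers, this r lay between -0.287 and 0.0713.

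The first question was how many crossovers a sperm carries. The autosomes of a sperm held 12.05 ± 2.50 crossovers (mean and SD over all sperm), with a median of 12 and a range of 5 to 21. The count varied much less than independent events would: the ratio of variance to mean was 0.517, against 1.0 (central 95%, 0.82 to 1.2) when the same total was dealt to the sperm at random. None of 100000 random assignments was as far from that mean, so the two-sided permutation p was 2.0e-05, the smallest they can give. No tendency of sperm with many crossovers on 1 chromosome to have many on others was detected. The variance of the total was 6.23, against 6.79 (central 95%, 5.61 to 8.04) when sperm were reshuffled separately for each chromosome, a ratio of 0.918 (two-sided permutation p = 0.386). A weak tendency that keeps the variance inside this central 95% would be missed. The mean per sperm was between 11.5 and 12.4 in the 5 runs of sperm numbers (permutation p = 0.508). In contrast, the geometric mean over sperm of their median interval width differed between the runs, from 757 to 1224.2 bp (permutation p = 0.00027).

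**Figure D1:**
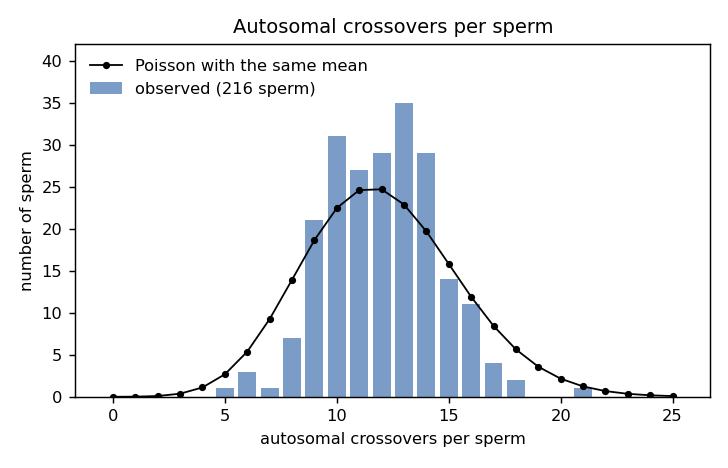
Bars show the number of sperm (y axis) with each number of autosomal crossovers (x axis), and the line shows a Poisson distribution with the same mean, 12.05. The sperm lie between 5 and 21 crossovers, a narrower spread than that of the line.

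Chromosomes differed in how much they recombined. Chromosome 19, the shortest autosome, had the highest rate, 0.846 crossovers per sperm per 100 Mb, followed by chromosome 11 with 0.668 and chromosome 18 with 0.644. The lowest rates were those of chromosome 3 with 0.330, chromosome 6 with 0.371 and chromosome 4 with 0.406. The autosomes as a whole gave 0.490. In exact binomial tests against the share of the genome, with Benjamini-Hochberg adjustment over 19 chromosomes, chromosomes 19 (112 crossovers against 64.8 expected, adjusted p = 1.3e-06), 11 (176 against 129, adjusted p = 0.00030) and 18 (126 against 95.8, adjusted p = 0.0095) were above the mean rate. Chromosomes 3 (114 against 169, adjusted p = 4.4e-05) and 6 (120 against 158, adjusted p = 0.0064) were below it, and chromosome 4 (137 against 165, adjusted p = 0.069) did not pass. Without the run of sperm numbers that starts with 4, chromosome 18 did not pass (adjusted p = 0.071), and without the run that starts with 2, chromosome 4 passed (adjusted p = 0.031). The chi-square over all 19 was 109, against a mean of 18.0 in draws proportional to length (permutation p = 1.0e-05, the smallest that 100000 draws can give).

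Longer chromosomes carried more crossovers per sperm, but fewer per Mb. The count per sperm rose from 0.5 on chromosomes 13, 15 and 16 to 0.903 on chromosome 1, and correlated with length over the 19 autosomes with r = 0.658 (permutation p = 0.0020) and rho = 0.600 (permutation p = 0.0079). Without chromosomes 1 and 19, the 2 farthest from the median length, r was 0.533 (permutation p = 0.028). The fitted line had a slope of 0.268 crossovers per sperm per 100 Mb (95% bootstrap interval over sperm, 0.212 to 0.325) and an intercept of 0.286 (0.213 to 0.363). The rate per 100 Mb fell with length, with r = -0.650 (permutation p = 0.0027), rho = -0.612 (permutation p = 0.0064) and r = -0.523 (permutation p = 0.031) without chromosomes 1 and 19. With the relation to interval width above, 3 such relations were computed, and the Benjamini-Hochberg adjusted p of r was 0.0040 for both relations to length and 0.399 for width. Within the 5 runs of sperm numbers, r of the count with length lay between 0.454 and 0.688, with p under 0.05 in 4 of 5 and a largest p of 0.052.

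**Figure D2:**
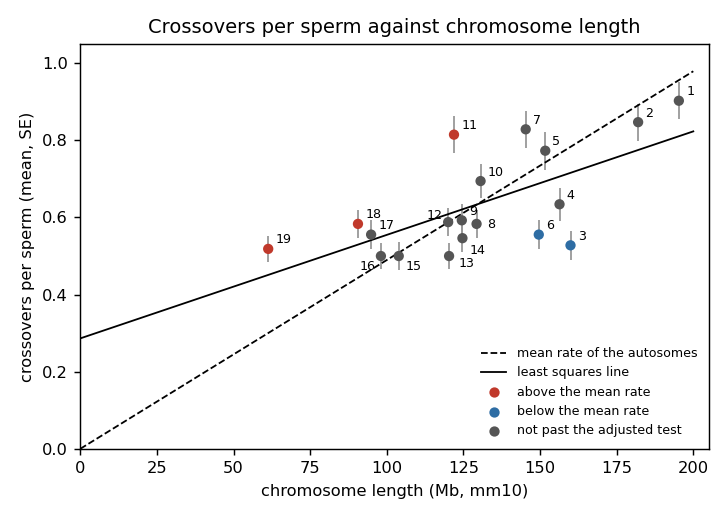
Each point is 1 autosome, with its length in Mb (x axis) and its mean number of crossovers per sperm (y axis, bars are the SE over sperm), the dashed line is the mean autosomal rate and the solid line the least squares fit. Chromosomes 11, 18 and 19 lie above the mean rate and chromosomes 3 and 6 below it.

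The spread along a chromatid addressed interference, the tendency of a crossover to keep others away. Of the 4104 autosomal chromatids, 1782 (43.4%, 95% Clopper-Pearson interval 41.9 to 45.0) had no crossover, 2049 (49.9%, 48.4 to 51.5) had 1, 266 (6.48%, 5.75 to 7.28) had 2 and 7 (0.171%, 0.0686 to 0.351) had 3. Those with 2 or 3 together were 0.495 times the 551 (central 95%, 525 to 578) obtained when the crossovers of each chromosome were assigned to sperm at random (two-sided permutation p = 2.0e-05). Exactly 2 crossovers were found on 42 chromatids of chromosome 1, 36 of chromosome 2, 35 of chromosome 5, 34 of chromosome 7 and 33 of chromosome 11. They were found on 6 and 7 of chromosomes 3 and 6, which are longer than chromosome 11, and on 1 each of chromosomes 13, 16 and 19.

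Where 2 crossovers shared a chromatid, they lay far apart. The 280 pairs of neighbours were separated by a median of 98.3 Mb (quartiles 76.3 and 119 Mb), against 42.7 Mb (central 95%, 35.3 to 50.2) when positions were reassigned between sperm within each chromosome (two-sided permutation p = 0.00020, the smallest that 10000 permutations can give). Only 12 pairs were under 20 Mb apart, against 86.6 expected (72 to 101, p = 0.00020), and 23 were under 50 Mb, against 155. As a share of the chromosome the median distance was 65.5%, against 29.1%. Of the 12 pairs under 20 Mb, 10 were at most 2.59 Mb apart and the next was at 11.3 Mb. Without the run of sperm numbers that starts with 3, the count under 20 Mb was 5, against 70.4.

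**Figure D3:**
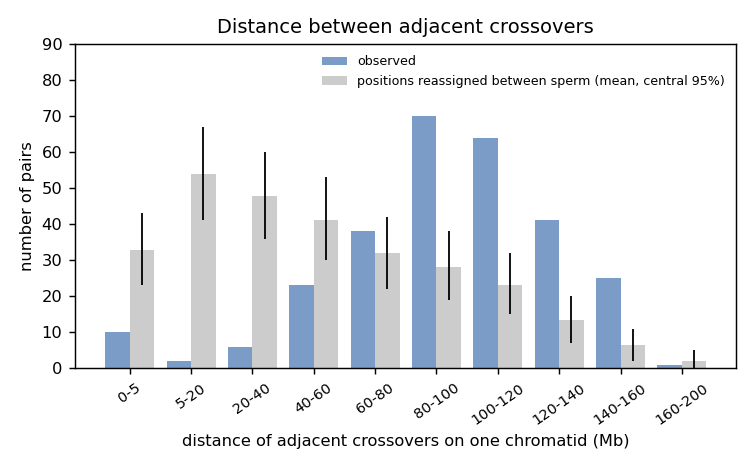
Pairs of adjacent crossovers on 1 chromatid (y axis) by their distance in Mb (x axis), observed and with positions reassigned between sperm (mean, bars give the central 95%). From 5 to 20 Mb there were 2 pairs against 53.8, and from 80 to 100 Mb there were 70 against 28.1.

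Crossovers gathered towards the telomere. Mouse autosomes have the centromere at their first end, so positions were counted from 3 Mb, where the assembled sequence begins. They ran to the largest coordinate of the genes and crossovers on each chromosome. The distal 20% held 1139 crossovers, 43.8% (95% Clopper-Pearson interval, 41.9 to 45.7), and the proximal 20% held 9.68% (8.58 to 10.9). Exact binomial tests against 20%, which took every crossover as independent, gave p = 1.2e-165 and p = 3.4e-46 (two-sided). The last 10% of the chromosome alone held 31.3% and the first 10% held 3.11%. The distal window held more crossovers than the proximal one on 19 of 19 autosomes, most unequally on chromosome 19 (64 against 1) and chromosome 15 (60 against 1) and least so on chromosome 14 (31 against 14). Only 2 sperm had fewer crossovers in the distal than in the proximal window and 12 had as many, and all the others had more.

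The medians of paired crossovers lay on either side of that of single ones. On chromatids with 2 crossovers, the distal one lay at a median of 95.2% of the chromosome and the proximal one at 23.8% (n = 266), whereas crossovers that were alone on their chromatid lay at 74.0% (n = 2049). Of the proximal ones, 13.5% were in the first 10% of the chromosome, 26.3% in the second and 26.3% in the third. Both differences passed a permutation test within chromosomes (two-sided p = 2.0e-05 each, the smallest 100000 permutations can give). The outer of 2 positions drawn at random is more distal than a single one, so the positions were also reassigned between sperm: the distal one was then expected at 91.0% (central 95%, 89.1 to 92.5) and the proximal one at 38.5% (34.4 to 42.1), with a permutation p of 0.00020 for each, the smallest that 10000 can give. This second comparison was added after the positions had been seen. It reassigned positions as the test of distances did, for pairs that were also in that test. It is therefore not independent of the wide spacing of pairs.

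**Figure D4:**
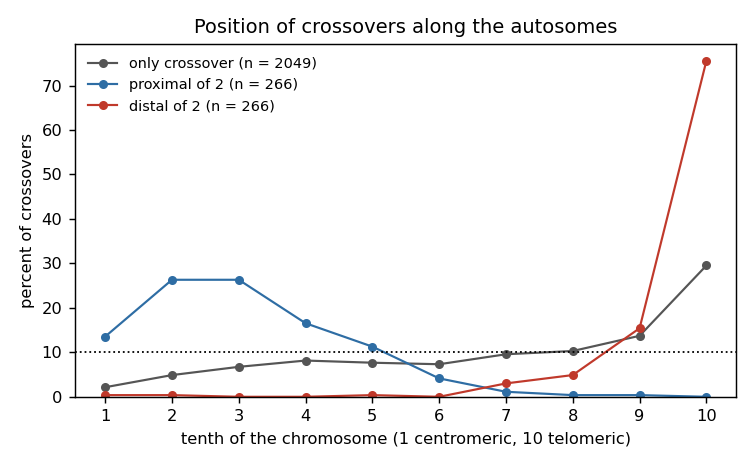
Percent of crossovers (y axis) in 10 equal parts of the autosomes from centromere to telomere (x axis), for crossovers alone on a chromatid and for the proximal and distal of 2, with a dotted line at 10%. The last part holds 75.6% of the distal crossovers of a pair and 29.5% of the single ones.

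Different sperm used the same sites. Among the 2459 autosomal intervals of up to 10 kb, 926 (37.7%) overlapped an interval of another sperm, against 25.96 (central 95%, 12 to 40) when every interval was moved by 50 to 500 kb, a ratio of 35.7 (one-sided permutation p = 0.0010, the smallest that 1000 sets can give). Within each of the 5 runs of sperm numbers the count was also above its expectation. The overlapping intervals formed 344 sites used by 2 or more sperm, and 32 sites with 5 or more sperm held 196 crossovers, 7.97% of the intervals. Because overlap depends on how many sperm and how narrow intervals are compared, the percentage is a property of this set.

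The busiest autosomal site lay in Gfra1, which encodes a receptor for glial cell line-derived neurotrophic factor, on chromosome 19 (58361768 to 58366037), where 10 sperm (4.63%, 95% Clopper-Pearson interval 2.24 to 8.35) had a crossover. A site on chromosome 1 (184610528 to 184619829) was used by 9 sperm (4.17%, 1.92 to 7.76), and the nearest protein-coding gene was Hlx, a homeobox transcription factor, 107 kb away. Another 9 sperm had crossovers at Nr4a1, an orphan nuclear receptor, on chromosome 15 (101260254 to 101280049). Runx1, a transcription factor of blood development on chromosome 16, held a site of 8 sperm (92782106 to 92784457). Another 8 autosomal sites had 7 sperm each (3.24%, 1.31 to 6.56), and the 5 with the smallest joint width were: chromosome 1 from 187021942 to 187023018 in Spata17, chromosome 17 from 93378140 to 93381132 at 172 kb from Adcyap1, chromosome 15 from 100300589 to 100304268 overlapping Mettl7a1, chromosome 8 from 108582044 to 108586192 in the transcription factor gene Zfhx3, and chromosome 5 from 147283135 to 147287611 at 7.29 kb from Pdx1, a transcription factor of the pancreas. Whether these positions lie in exons was not analysed here. The sites were chained from overlapping intervals and picked for their number of sperm, so their shares may be too high.

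On the X chromosome, crossovers were confined to its far end. In a male, the X recombines with the Y only in the pseudoautosomal region, so a restriction of this kind follows from the design. All 34 lay between 169593763 and 169927806, a stretch of 334 kb that ends 0.750 Mb before the end of the last annotated gene of the chromosome. They came from 34 sperm (15.7% of all, 95% Clopper-Pearson interval 11.2 to 21.3). Of these, 32 were inside Mid1 (169685199 to 169990798), a gene for a microtubule-associated ubiquitin ligase that spans the boundary of the pseudoautosomal region in laboratory mice, and 2 lay on its proximal side, between 169593763 and 169600831. Where in Mid1 this boundary lies, and whether CAST has the same one, is not given in the sources used here. How many of the 34 lie beyond the boundary of laboratory mice was therefore not determined, and the 2 proximal to Mid1 do not. The density was 47.1 crossovers per Mb per 100 sperm, 96.2 times the autosomal 0.490, in a stretch whose bounds were set by the crossovers themselves. Its busiest site, from 169877191 to 169883082, was used by 12 sperm (5.56%, 2.90 to 9.50) and was the most used site of all. The bounds of this site are those of 1 interval of 5891 bp, which chained narrower ones that need not overlap each other. X crossovers occurred in all 5 runs of sperm numbers, in 12.8% to 18.9% of the sperm. Sperm with one had 11.6 ± 2.79 autosomal crossovers (SD, n = 34) and those without 12.1 ± 2.44 (n = 182), a difference that did not pass a permutation test (p = 0.312). Which sperm carried the X and which the Y is not known from the values used here. Marker positions are not known either, so crossovers beyond the listed stretch could have been missed and 15.7% may be too low.

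**Figure D5:**
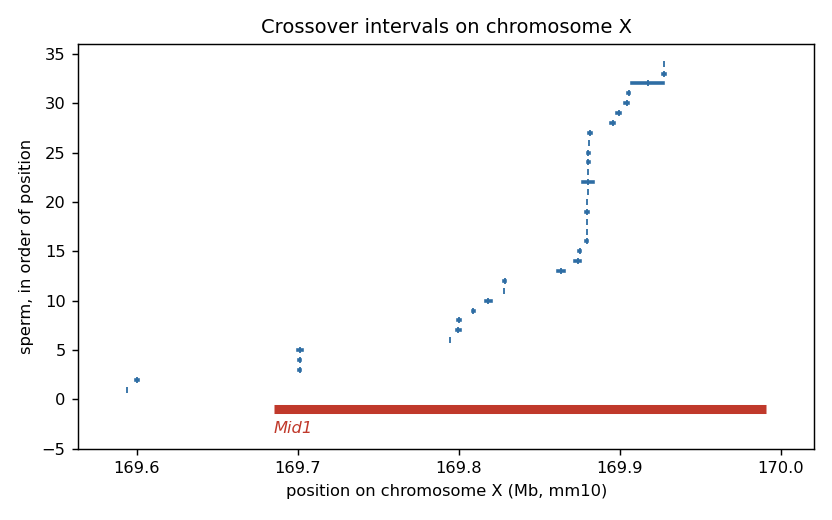
Each line is the crossover interval of 1 sperm on the X chromosome (x axis, position in Mb on mm10), stacked in order of position (y axis), with the extent of Mid1 in red. Of the 34 intervals, 32 lie inside Mid1 and 12 at 1 site within it.

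Counted over whole genes, Mid1 led with 32 intervals entirely inside it. It was followed by Gfra1, Runx1 and Esrrg, an orphan nuclear receptor, with 11 each, then by Plch2, a phospholipase C, and Dscam, a neuronal adhesion molecule, with 9 each. Nr4a1, Spata17, Sorcs3, Zfhx3 and the transcription factor Sox5 held 8 each, and Tcf7l2, a transcription factor of the Wnt pathway, Atxn7l1 and the teneurins Tenm2 and Tenm3 held 7 each. Tekt3, a tektin of the sperm flagellum, Gpr161, the skeletal muscle calcium channel gene Ryr1, Gse1 and Arl15 held 6 each. Gene length differed widely among them: Nr4a1 spans 20.9 kb, which made 383 intervals per Mb, and Tenm3 spans 1297 kb, with 5.40 per Mb. Under a uniform density, 0.0221 intervals would fall in Nr4a1 and 1.37 in Tenm3. The genes were picked for their counts and crossovers were not uniform along the chromosomes, so these expectations are no test. In all, 709 protein-coding genes held at least 1 whole interval and 40 held 5 or more.

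Gene bodies took slightly fewer crossovers than their surroundings. Of the 2459 intervals of up to 10 kb, 57.1% had their midpoint in an annotated gene, against 59.4% (central 95%, 57.7 to 61.0) after moves of 20 to 200 kb (two-sided permutation p = 0.0080, adjusted p = 0.016 over 2 tests). Each interval was moved on its own, although 926 overlapped one of another sperm. The central 95% may therefore be too narrow, and p-values of this kind too small. The direction depended on the distance of the move: after moves of 200 kb to 2 Mb the expectation was 54.8%, below the observed value (p = 0.024). For protein-coding genes alone the share was 49.0% against 49.9% and did not pass (p = 0.306). Within 2 kb of either end of a protein-coding gene lay 7.89% of the midpoints, against 7.06% (p = 0.0879, adjusted p = 0.0879). The outcome of this test varied with the runs of sperm numbers included: the share was 9.63%, against 7.31%, within the first run (unadjusted p = 0.010), and 7.08%, against 6.99%, without it (p = 0.909); of the other 4 omissions, only that of the fifth run passed, with 8.13% against 6.94% (p = 0.038).

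Of 8 gene lists fixed before the data were examined, 3 departed from the numbers obtained by moving all 2602 crossovers by 1 to 5 Mb. Olfactory receptor genes (1420 genes) had 4 crossovers within 10 kb, against 23.0 (central 95%, 14 to 32), and vomeronasal receptor genes (623 genes) had 2, against 14.4 (8 to 21.0). Both are large clustered families of chemosensory receptors, and none of their members held a crossover midpoint within the gene itself. Protein-coding genes longer than 500 kb had 230, against 180 (156 to 203.03). Each had an adjusted p of 0.0053 over the 8 lists (two-sided permutation, Benjamini-Hochberg), from a raw p of 0.0020 that is the smallest 1000 sets can give. Crossovers at a shared site were moved separately here too, so these p-values may be too small. With the gene body alone, without the flanking 10 kb, the olfactory receptors had 0 crossovers against 2.37 and did not pass (adjusted p = 0.335). Without the fourth run of sperm numbers, genes over 500 kb had 175 against 146 (two-sided permutation, adjusted p = 0.037). Omission of any other run left an adjusted p of 0.0080 or less. The lists were moved by 1 to 5 Mb only, so whether their results depend on the distance, as that of gene bodies did, was not tested.

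Among the long genes, 83 held at least 1 midpoint, led by Esrrg with 11, Dscam with 9 and Sorcs3, Sox5 and Zfhx3 with 8 each. The other 5 lists did not pass. Zinc finger protein genes had 26 crossovers against 24.9 (adjusted p = 0.895), with 5 midpoints in Zfp423, 3 in Zfp385b and 2 each in Zfp385c, Zfp407, Zfp516 and Zfp563. Protocadherins had 1 against 3.01 (adjusted p = 0.691), in Pcdh15. Hox genes had 2 against 1.21 (adjusted p = 0.895), in Hoxd3 and Hoxb3os. Major histocompatibility genes had 0 against 0.781 (adjusted p = 0.895), and 42 meiotic recombination genes had 2 against 3.56 (adjusted p = 0.895), with none inside a gene.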

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

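The alternatives that count both lists of the doubled sperm, the measure of distance to gene ends, the reassigned positions of paired crossovers, and the omission of each run of sperm numbers from the tests on genes and paired crossovers were chosen after seeing the data; the rest were fixed before. Over 26 results, 191 alternatives were counted as unchanged and 13 as changed. Some could hardly change, such as r with length after the first 3 Mb were taken off every chromosome, so the tally is no measure of robustness. A result with a test was unchanged if it kept its direction and its side of the threshold, and a value without a test if it moved by less than its spread. For the crossovers at shared sites and the chromosomes off the mean rate, the count also had to stay within 1.5 times the main one. For other counts with a test it did not. The pairs under 20 Mb fell from 12 to 5 without the fourth run of sperm numbers and to 1 without crossovers closer than 5 Mb. Olfactory receptors rose from 4 to 16 (against 44.7) with flanks of 100 kb. Vomeronasal receptors rose from 2 to 9 (against 34.7) with these flanks and fell to 0 (against 12.5) without the fifth run. With intervals of up to 2 kb, the crossovers at shared sites were 617 against 6.74 expected, and without the first run of sperm numbers they were 504 against 12.1. Both have fewer intervals to compare, 1898 and 1680, each with a one-sided p of 0.0020, the smallest that 500 sets can give. The share in gene bodies, 57.1%, was below its expectation after moves of 20 to 200 kb and above it, 54.8%, after moves of 200 kb to 2 Mb, and the 49.0% for protein-coding genes did not pass; the cause was not tested. With the flanks of 100 kb in place of 10 kb, zinc finger genes turned to 73 crossovers against 80.8, major histocompatibility genes to 3 against 2.28 and meiotic genes to 21 against 13.6. With intervals of up to 10 kb, Hox genes turned to 1 against 1.17, and without the second run of sperm numbers to 1 against 1.06. Zinc finger genes turned to 19 against 20.3 without the fourth run and to 19 against 20.7 without the fifth. None of these 4 lists passed the test in the main result or in these alternatives. Near gene ends, 8.13% against 6.94% passed without the fifth run (unadjusted p = 0.038), where the main result did not, and without the first run the share was 7.08% against 6.99% (p = 0.909). Within single runs it was above expectation in 3 and below in 2, and passed only in the first, with 9.63% against 7.31% (p = 0.010). The chromosomes off the mean rate were 5 in the main result, 4 without the fifth run, which lost chromosome 18 (adjusted p = 0.071), and 6 without the third, which gained chromosome 4 (adjusted p = 0.031). Inside the gene alone, olfactory receptors had 0 against 2.37 (adjusted p = 0.335), where few crossovers are expected. Within single runs of sperm numbers, the variance to mean ratio was 0.452 to 0.536, the median distance 92.0 to 104 Mb and the distal share 40.7% to 47.6%, all past the test in 5 of 5 runs. Of the gene tests that passed over all runs, fewer passed within single runs, which hold fewer crossovers: the share in gene bodies was below expectation in 5 runs and passed in 0, olfactory receptors were below in 5 and passed in 2, vomeronasal receptors were below in 4 and passed in 1, and genes over 500 kb were above in 5 and passed in 2 (unadjusted p). The planned tests on GC content, the PRDM9 motif, 8-base sequences, exons, gene starts and parental haplotype were not run. Unknown depth and marker density limit what the missing close pairs and narrow intervals can show.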

Other observations

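The tests on the doubled sperm and on close pairs were chosen only after the result was seen, as were the values by chromosome for receptor genes; the tests of wide intervals and of position for receptor genes were set out before.

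Long stretches had no crossover in any sperm. The longest ran on chromosome 13 from 3 Mb, the start of the assembled sequence, to 23.3 Mb. It contains 156 protein-coding genes and 88 olfactory or vomeronasal receptor genes and pseudogenes, and 7.84 crossovers would fall there if chromosome 13 followed the positions on the other autosomes. Chromosome 3 had 2 such stretches, from 9.05 to 27.9 Mb (5.54 expected) and from 36.1 to 51.8 Mb (9.85 expected), and so had chromosome 1, from 93.7 to 106.3 Mb (9.48 expected) and from 106.3 to 119.4 Mb (8.67 expected). The most gene-rich of the 10 longest lay on chromosome 7 from 98.9 to 112.8 Mb, with 349 protein-coding genes, 240 receptor genes or pseudogenes and 13.2 crossovers expected. The stretches were picked for their length, so no test is attached to these expectations.

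The sperm with the most crossovers had 21, and the next had 18. The former had 4 chromosomes with 2 or more crossovers, none closer than 39.2 Mb, and a median interval width of 715 bp.

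Crossovers were few near chemosensory receptor genes. Over both families, 2043 genes with 10 kb on either side covered 39.0 Mb and held 6 midpoints, against 37.4 in sets moved by 1 to 5 Mb. If markers were lost in these repeated families, crossovers there would be listed with wide intervals that touch the regions; only 9 intervals touched them, against 39.7 (central 95%, 28 to 51), which argues against this as the whole cause. The place of the clusters along the chromosome predicts 36.9 crossovers, above the 95% Poisson interval of the observed 6 (2.20 to 13.1). The shortage does not rest on chromosome 7 alone, where 0 were found against 11.7: without it there were 6 against 25.7 (two-sided permutation p = 0.0020, the smallest possible), and 10 of the 10 chromosomes that expected at least 1 were below expectation. Of the 6 midpoints, 4 were on chromosomes that expected fewer than 1: 2 on chromosome 1 (0.402 expected) and 2 on chromosome 18 (0.0090 expected). Loss of whole segments by a filter stays open, and no biological explanation was tested. The moved sets also treated crossovers at a shared site as independent, so their spread may be too narrow.

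Pairs of crossovers less than 5 Mb apart may include errors of individual libraries. There were 10 such pairs on 9 chromatids, as 2 of them shared a crossover. With these 2 counted once, they made up 81.8% of the pairs under 20 Mb, against 37.8% in reassigned positions (one-sided binomial p = 0.0038), which argues against a reduction that is equal at every short distance. The 9 chromatids fell in 7 sperm, 2 of which held 2 each, fewer than the 8.83 sperm of random assignment (one-sided permutation p = 0.010), and 6 of the pairs were in the run of sperm numbers that starts with 3. A few noisy libraries could give such a gathering. The random assignment took no account of the runs, so it cannot separate single libraries from a gathering by run. The 2 sperm with 2 such chromatids each had median interval widths of 1516 and 632 bp, on either side of the 915.5 bp over all intervals. No other measure of noise per library was available. The intervals of the pairs had a median width of 1984 bp, against 957 bp in draws from the same sperm (two-sided permutation p = 0.083), so the values cannot tell whether poorly resolved breakpoints contribute. Genuine close crossovers or short conversions within the same sperm stay open, as no biological explanation was tested.

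The pair of sperm with shared crossovers may be DNA of 1 cell in 2 libraries. All 11 autosomal crossovers of the shorter list lay within 200 kb of one in the longer, whereas no other pair of sperm shared more than 4, which argues against chance use of common sites. The 8 autosomes without a crossover in the shorter list also lacked one in the longer (probability 0.00067 for unrelated sperm, and 0.0039 for 2 sperm of 1 meiosis at an even chance per chromosome). If so, the lists repeat 1 set of calls: 8 of 11 intervals overlapped and 3 did not (27.3%, 95% Clopper-Pearson interval 6.02 to 61.0), with gaps of 3.88 to 78.4 kb, so some breakpoints of these 2 lists may lie outside their listed bounds. Both are poorly resolved, with median widths of 3409 and 2689 bp against 915.5 bp over all intervals, and only 4 and 6 sperm had wider medians, so this share need not hold for other sperm. The 2 crossovers found in the longer list only were 1.13 Mb apart on chromosome 4, a close pair that the other list lacked.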
